A study of Mus musculus with 8 samples.

How the data were processed

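The data were CEL-seq2 libraries of single mouse bone marrow cells from the LSK gate, the Sca1- and cKit-positive marrow fraction that holds blood stem cells and early progenitors, taken from mice that carry a GFP reporter in the Dach1 gene. Dach1 encodes a transcriptional cofactor, and in these mice GFP is made from the same transcript as the Dach1 protein, per the labels' protocols. CEL-seq2 copies the 3' end of polyadenylated RNA from each cell, tags every copy with a cell barcode and a random molecular tag, and amplifies the pooled copies of a plate by transcription. The deposited count tables held 1 whole number per gene and well for each of 8 plates of 383 wells, and per the labels the plates fall into a set of 4 named LC and a set of 4 named LCE. Plates LC187 to LC190 are called replicates 1 to 4 here, and LCE409, LCE407, LCE408 and LCE410 replicates 5 to 8. The labels do not say which animals the cells of a plate came from, so p-values measure the spread between plates, which may be partly technical.

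What the authors did between reads and counts was only partly recorded in the sources used here. The submitters' processing notes name the genome build GRCh38, a human assembly, while every gene identifier in the deposited counts is a mouse Ensembl identifier, so no coordinates are printed. The aligner, the counting tool, the use of strand and the treatment of the molecular tags are not given in the sources used here. The highest count of a gene in a well was 1532, below the 4096 tags that 6 bases can form, so the values do not tell reads from molecules and are called counts. Near-identical genes (the H2A histone genes, alpha and beta globin genes, Ifitm genes, Ly6c genes and immunoglobulin segments) could share counts, and their values are uncertain. The second kind of deposited value was the fluorescence intensity of each sorted cell on the sorter's linear scale, per the file headers, with values below 0 that show that background or compensation had been subtracted before deposit. All 8 plates had Dach1-GFP, CD135, CD150, Sca1, cKit, IL7R and CD11b. Forward scatter (FSC-A), side scatter (SSC-A), CD48, CD16/32 and PIR-A were used on the LCE plates alone. 1 plate of the sorter's records had no index values and was not used.

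Gene symbols came from the supplied gene name table, which matched 27249 of 27318 identifiers. Spike-in RNA made 3.27% to 4.36% of counts on the LC plates, was absent from the count tables of the LCE plates, and was left out of library sizes and tests. Of 2987 wells with both a count column and a sort record, 2712 were kept: each needed 1000 counts, 500 genes and under 20% of counts from the mitochondrial genome. Kept cells numbered 1360 on the LC and 1352 on the LCE plates, 335 to 340 per plate. 13 sort records of the LCE plates were in wells with no barcode. Wells that got no cell, 3 per plate, held at most 42 counts, and no doublet caller was run because each well got 1 sorted cell. The total of kept counts per plate ranged from 2091816 to 5192543.

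Cells are not replicates, so counts were summed per plate and arm. Within each plate, the lowest and the highest tercile of the cells by fluorescence formed the arms, with at least 10 cells in each. The comparisons were GFP low against high, CD135 high against low, CD150 high against low, and GFP low against high among cells above their plate's median CD135. The interaction of GFP with CD135 used 4 sums per plate, split at both plate medians, and the additive fit of the same sums gave each effect adjusted for the other. All comparisons reuse the same cells, so shared calls between them are not independent evidence. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test, plate as a block) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Adjusted p-values of single genes are from this test unless another is named. The direction is stated with each comparison, and ± after a log2 difference is its standard error, while ± after CPM (counts scaled to the total of their plate and arm) is the SD over plates. The arms are paired by design, since both come from the same plate. The arms of a plate deviated together from the arm means over all plates (correlation 0.334 to 0.651 over plates and comparisons). The difference between LC and LCE plates enters these values, so they do not show how far the arms of a single plate go together. Values within LC or LCE plates are from each set fitted alone, except those of F13a1 and Ifi27l2a by GFP, Slc35d3 by GFP among CD135-high cells, Ly6a, Il7r and Fcgr3 by CD135, and Car1 and Esam by CD150, which are from a fit of both sets with a term for the set. Values of single genes per set among the results flagged for a closer look are from that joint fit too. For transcripts of sorted proteins, log2 ratios within a set are means over its plates.

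Genes are named by a rule: Dach1 and the genes of the sorted proteins; up to 10 genes higher and 10 lower with the largest change among those past the threshold, with a mean log2 CPM of 4 or more and the same direction on every plate; and up to 4 members of each list by adjusted p. Rises and falls called largest are so within these limits of expression and direction. A few genes that the rule names are not reported here. The 17 lists held lymphoid priming, stem cell, granulocyte and monocyte, erythroid, megakaryocyte, dendritic cell, mast cell with basophil and eosinophil, mature B cell, T and NK cell, mature neutrophil, macrophage, S phase, G2 and M phase, immediate early with heat shock, interferon response, ribosomal protein and mitochondrially encoded genes. The ribosomal list was a name pattern that also takes in kinases such as Rps6ka3. The comparisons, arms, lists, naming rule and all alternatives but those named as chosen later were set before the data were examined. A list needed 3 tested genes, and the gene of the sorted protein was left out of its own comparison. The T and NK cell and mature neutrophil lists never reached 3 tested genes, the mast cell list did so only in the fits of GFP with CD135 and by cKit, and the macrophage list only in those fits and by CD150, Sca1 and cKit. Lists were tested with fry, which asks whether a list's genes move, on balance, one way, and with camera of limma 3.58.1, which compares a list with all other genes, with a preset correlation of 0.01 and with an estimated one. Neither fry value compares a list with other lists.

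The gene of each sorted protein was compared between arms with an exact two-sided sign-flip permutation test over plates, on log2 ratios of CPM with 0.5 added counts. For clusters, scanpy 1.11.5 used 2000 variable genes, 30 principal components, 15 neighbours and Leiden (igraph 0.11.9) at resolution 1. The genes of the sorted proteins, Dach1, and spike-in, mitochondrial and ribosomal genes were left out of that step. A cluster was named only with at least 3 markers of a list among its higher genes, and only if no other list had more markers among its top 10 genes. Fluorescence was compared on the arcsinh scale (divisor 150) with the same exact test, over plates with at least 10 cells of the cluster. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.

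The tests of single genes were tried on simulated data with 200 changed genes. Apart from depth, the simulated sums had no differences between plates, and every gene had the same dispersion. Changed genes came from those with more counts. The interaction used the dispersion of the GFP comparison, and unchanged lists held genes simulated independently. Recovery and false calls in the real data can therefore be worse than given here. For the GFP comparison, 76.1% of genes changed 1.5-fold, 97.0% of those changed 2-fold and all of those changed 4-fold were recovered, with 10 false calls among 206. For CD135 and CD150, 62.7% and 73.1% of 1.5-fold changes were recovered (13 false calls among 196 and 4 among 189), and for GFP among CD135-high cells 56.7% (13 among 188). For the interaction, 32.8% of 1.5-fold and 77.6% of 2-fold changes were recovered (6 false calls among 145). Of 100 unchanged lists, fry gave an unadjusted p under 0.05 for 3 to 9 per comparison. For the clustering step, 800 cells were simulated, a part of them with 150 strongly raised genes, and clustered at a lower resolution than the real cells. All of them (100%) lay in clusters that held a single simulated group, which does not test the resolution used for the real cells.

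Alternatives were size factors by the median of ratios, DESeq2 1.42.0, no filter on genes, no plate block, arms split at the median or the outer quintiles, other filters on cells, each cell thinned to 3000 counts, fluorescence corrected for scatter (LCE plates), each plate left out, either plate set alone, other CD135 and CD150 limits, and other clustering settings. Thinning left out the 40 cells under 3000 counts, with 26 of them in the GFP-low and 6 in the GFP-high arm. Chosen after the data were seen, the counts were also repeated without cells of other types that the gate held: 86 cells with at least 5 counts over B cell genes that include Cd79a, Cd79b and Ms4a1 (called B lineage cells here), and 25 cells with at least 20 counts of plasma cell (Igkc and Jchain), mature neutrophil, globin or platelet genes, 107 cells together. Also chosen then were the lists of the fits of GFP with CD135 without these cells, and the G2 and M phase list with corrected against recorded fluorescence on the LCE plates alone.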

Results

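Single cells from the LSK gate of the bone marrow of Dach1-GFP mice were profiled by CEL-seq2 on 8 plates, and the sorter recorded the fluorescence of each cell before it was lysed. GFP stands for transcription of Dach1, a gene for a nuclear cofactor that regulates transcription. CD135 is the receptor for the FLT3 ligand, encoded by Flt3, and is carried by multipotent and lymphoid-primed progenitors. CD150, encoded by Slamf1, is carried by long-term stem cells and by megakaryocyte and erythroid progenitors. After filtering, 2712 cells remained, 335 to 340 per plate. Median counts per cell were 11586 to 13398 on the 4 LC plates and 5627 to 7525 on the 4 LCE plates, and the median number of genes detected per cell was 2481 to 3938.5. The labels give a single population with no treatment, so each comparison was made within plates, between cells with low and high fluorescence of a sorted protein. The question, as the series title frames it, was whether cells with little Dach1 within the LSK gate are primed for the lymphoid lineage.

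For 8 sorted proteins the transcript was tested, and on average over plates it was higher in the cells with more of the protein. No transcript was tested for CD11b and PIR-A. Dach1 was 51.7 ± 16.8 CPM in GFP-high and 12.6 ± 7.23 CPM in GFP-low cells, a log2 ratio of 2.13 ± 0.63 (SD, n = 8 plates, 1.73 within LC and 2.53 within LCE plates). Flt3 was 311 ± 72.3 CPM in CD135-high and 77.8 ± 32.6 CPM in CD135-low cells, a log2 ratio of 2.07 ± 0.36. Slamf1 was detected at a low level, 4.55 CPM in CD150-high and 0.675 CPM in CD150-low cells, with a log2 ratio of 2.02 ± 0.87. Ly6a, which encodes Sca1, had a log2 ratio of 2.0 ± 0.51, and Kit, which encodes the receptor for stem cell factor, had one of 0.33 ± 0.15. These 5 transcripts were higher on 8 of 8 plates, each with p = 0.0078 by the exact sign-flip test, the smallest that 8 plates can give, and an adjusted p of 0.0125 over 8 transcripts. Il7r, the gene of the interleukin-7 receptor, was higher with its protein on 7 of 8 plates (log2 ratio 2.20 ± 1.5, exact p = 0.0156, adjusted p = 0.0208), and had 0 counts in both arms of replicate 4. Cd48 (1.41 ± 0.17) and Fcgr3 (1.68 ± 1.38) were higher on 4 of 4 LCE plates, where the smallest exact p is 0.125. Fcgr3 had 0 counts in the low arm of replicates 5 and 8.

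**Figure D1:**
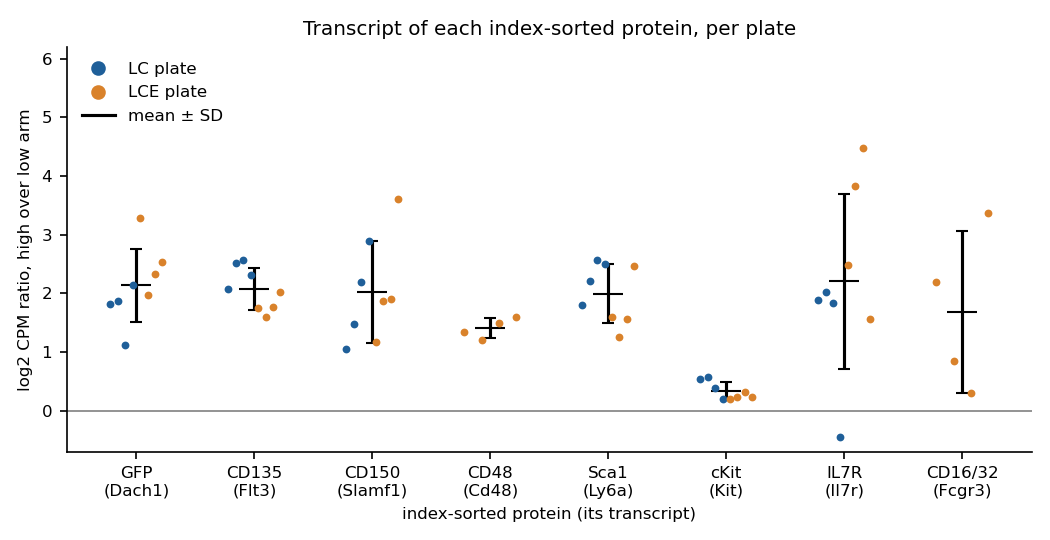
Log2 ratio of CPM between the high and the low arm (vertical axis) for the transcript of each sorted protein (horizontal axis), with 1 point per plate, LC plates in blue and LCE plates in orange, and black bars for the mean ± SD. Dach1, Flt3, Slamf1, Ly6a and Kit lie above 0 on all 8 plates, and Il7r lies below 0 on 1 plate, where it had 0 counts in both arms.

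Cells with low Dach1-GFP held more RNA of lymphoid priming genes, and less of stem cell and megakaryocyte genes, than cells with high GFP. Dntt, which encodes the terminal transferase that adds bases at joints of antigen receptor genes, was 487 ± 188 CPM in GFP-low and 85.9 ± 46.6 CPM in GFP-high cells (log2 difference 2.55 ± 0.07, SE, low minus high, edgeR adjusted p = 4.3e-34). Slc18a2, which encodes a vesicular monoamine transporter of mast cells and basophils, was 8.04 ± 5.68 CPM in GFP-low and 43.3 ± 8.02 CPM in GFP-high cells (-2.60 ± 0.21, edgeR adjusted p = 2.3e-14). Dach1 itself differed by -1.95 ± 0.16 (edgeR adjusted p = 4.7e-14). Each of these 3 differences had the same sign on 8 of 8 plates. In all, 801 of 10314 genes passed, 395 higher and 406 lower in GFP-low cells.

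Among the largest rises in GFP-low cells, Cd74, the invariant chain of MHC class II, differed by 2.48 ± 0.12, and Ccr9, a chemokine receptor that guides cells to thymus and gut, by 2.29 ± 0.21. Irf8, a transcription factor of dendritic and B cells, differed by 2.17 ± 0.11, Mpeg1, the gene of perforin-2, by 2.16 ± 0.19, and Cmah, a sialic acid hydroxylase gene, by 2.33 ± 0.18. All 5 were higher on 8 of 8 plates. Within the LC and the LCE plates the differences were 2.72 and 2.39 for Dntt, 2.89 and 2.11 for Cd74, and 2.30 and 1.88 for Irf8. Flt3 was 291 ± 95.1 CPM in GFP-low and 105 ± 42.1 CPM in GFP-high cells (1.5 ± 0.07, 1.62 on LC and 1.39 on LCE plates). Kit went the other way, 190 ± 21.2 against 270 ± 30.6 CPM (-0.52 ± 0.06, -0.56 on LC and -0.44 on LCE plates), while Ly6a rose by 0.56 ± 0.11. Cd48 (-0.15 ± 0.08, edgeR adjusted p = 0.36) and Fcgr3 (0.09, edgeR adjusted p = 0.90) did not pass. The largest falls besides Slc18a2 and Dach1 were in the uncharacterised gene 4930519L02Rik (-2.02 ± 0.22), Pf4, platelet factor 4 (-1.96 ± 0.21), Mmrn1, multimerin 1 of platelets and endothelium (-1.81 ± 0.22) and the scaffold gene Shank3 (-1.80 ± 0.21). They were followed by the protocadherin gene Pcdh7 (-1.78 ± 0.25), Hdc, which makes histamine (-1.78 ± 0.24), Itga2b, the platelet integrin CD41 (-1.77 ± 0.15), and Cpa3, a mast cell carboxypeptidase (-1.74 ± 0.14).

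Genes of B lineage cells were also higher in GFP-low cells, and the gate held a few cells of that lineage. Cd79a, a signalling chain of the B cell receptor, differed by 3.36 ± 0.21, Igll1, the surrogate light chain of pre-B cells, by 3.09 ± 0.26, Blnk, an adaptor of B cell receptor signalling, by 2.13 ± 0.20, and Igkc, the kappa light chain constant region, by 2.35 ± 0.10. The 86 B lineage cells made up 3.17% of the cells, and 79 of them lay in the GFP-low and 2 in the GFP-high arm. Without these and the 25 cells rich in plasma cell, neutrophil, globin or platelet RNA, 742 genes passed, Dntt differed by 2.51, Cd74 by 1.97, Irf8 by 2.15 and Blnk by 1.29, and Igkc by 0.32 (edgeR adjusted p = 0.0999). Cd79a and Igll1 then had too few counts to be tested, and for Cd79a this follows from how the cells were chosen. Pf4 had 31% of its counts in a single cell and differed by -1.05 without these cells.

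The lymphoid priming list rose in GFP-low cells and the stem cell list fell. Lists given with a fry call, here and in the later comparisons, were also called by camera with an estimated correlation, except where that p is given. Of 17 lymphoid priming genes tested, 14 were higher and 0 lower, and adjusted over the list alone 15 were higher and 1 lower (median 1.30, fry adjusted p = 2.6e-06). Ighm, the heavy chain of IgM, differed by 1.98 ± 0.08, and Satb1, a chromatin organiser of lymphoid cells, by 1.30 ± 0.08. Without the 107 cells of both kinds, 11 of 15 lymphoid priming genes were higher and the median was 1.15. Of 17 stem cell genes, 16 were lower and 0 higher, and adjusted over the list alone 17 were lower (median -0.99, fry adjusted p = 1.2e-06). Gata2, a transcription factor of stem and mast cells, was 58.1 ± 9.07 against 143 ± 25.6 CPM (-1.32 ± 0.09), Apoe, which encodes apolipoprotein E, differed by -1.67 ± 0.12 and Angpt1, angiopoietin 1, by -1.04 ± 0.08, all lower on 8 of 8 plates.

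Lists of other lineages moved up, down or in no single direction. All 5 mature B cell genes tested were higher (median 2.13, fry adjusted p = 4.2e-06), among them the MHC class II genes H2-Aa (1.70 ± 0.11), H2-Eb1 (2.13 ± 0.14) and H2-Ab1 (1.21 ± 0.09), whose counts may be shared within the family. All of these 3 genes are also made by dendritic cells and macrophages. Of 5 dendritic cell genes, 3 were higher, and 4 when adjusted over the list alone (median 0.69, fry adjusted p = 1.2e-06), with Tcf4, the transcription factor of plasmacytoid dendritic cells, at 0.69 ± 0.06 and Ly6d, a surface protein of lymphoid progenitors, at 3.36 ± 0.31. Of 6 megakaryocyte genes, 4 were lower, the same number adjusted over the list alone (median -0.91, fry adjusted p = 0.000253), including the tetraspanin gene Cd9 (-1.34) and the transcription factor gene Fli1 (-0.48). The granulocyte and monocyte list had 3 of 17 genes higher and 3 lower, and 6 and 5 adjusted over the list alone. Its median was -0.05, its mean 0.20 and its fry direction downward (fry adjusted p = 0.743). F13a1, coagulation factor XIII of monocytes (2.18 ± 0.21, higher on 6 of 8 plates, 2.26 on LC and 0.13 on LCE plates), Clec12a, a myeloid lectin (1.19 ± 0.14), and Csf1r, the M-CSF receptor (1.40 ± 0.25), rose, and Nkg7, a granule protein gene, fell (-0.61 ± 0.09). The erythroid list had 5 of 11 genes higher and 2 lower, and 5 and 3 adjusted over the list alone (median 0.33, fry adjusted p = 0.743). The globin gene Hba-a2, with 33% of its counts in 1 cell, differed by 1.98 ± 0.28, and by 0.20 without the 107 cells.

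Of the remaining lists, the G2 and M phase genes were 0 higher and 4 lower of 16, 9 lower adjusted over the list alone (median -0.22, fry adjusted p = 0.0857). Ube2c, a ubiquitin enzyme of mitotic exit, differed by -0.50 ± 0.10 (-0.65 on LC and -0.13 on LCE plates), and Top2a, topoisomerase II, by -0.20 ± 0.05 (-0.30 on LC and 0.01 on LCE plates). S phase genes were 1 higher and 1 lower of 16 (fry adjusted p = 0.237). The immediate early and heat shock list (1 of 7 higher, fry adjusted p = 0.0201), the interferon list (1 of 8 higher, fry adjusted p = 0.0141) and the ribosomal list (11 of 95 higher, 1 lower, fry adjusted p = 0.0201) were each called by fry alone. With an estimated correlation they had an adjusted p = 0.237, adjusted p = 0.244 and adjusted p = 0.272. Adjusted over the list alone, these 3 lists had 2, 2 and 14 genes higher, the last with 1 lower. Btg2, an antiproliferative immediate early gene, differed by 1.03 ± 0.18, Ifi27l2a, an interferon-induced gene, by 1.04 ± 0.25 (0.48 on LC and 1.71 on LCE plates), and Rps9 of the small ribosomal subunit by 0.11 ± 0.02. The mitochondrially encoded list had 4 of 19 genes higher (fry adjusted p = 0.0616).

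In the LC plates alone 450 genes passed, and in the LCE plates alone 490. The count was 198 without the plate block, 444 by DESeq2, 272 with each cell thinned to 3000 counts and 527 with GFP corrected for scatter on the LCE plates, where Top2a (0.47), Ube2c (0.57), Cks2 (0.14) and Hmgb2 (0.39) were higher in the GFP-low arm, against 0.0054, -0.13, -0.21 and -0.09 with GFP as recorded on the same plates. Of the 801 genes, 362 were called with the same sign under that correction and 17 with the opposite sign. With GFP as recorded on the LCE plates these numbers were 391 and 0.

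**Figure D2:**
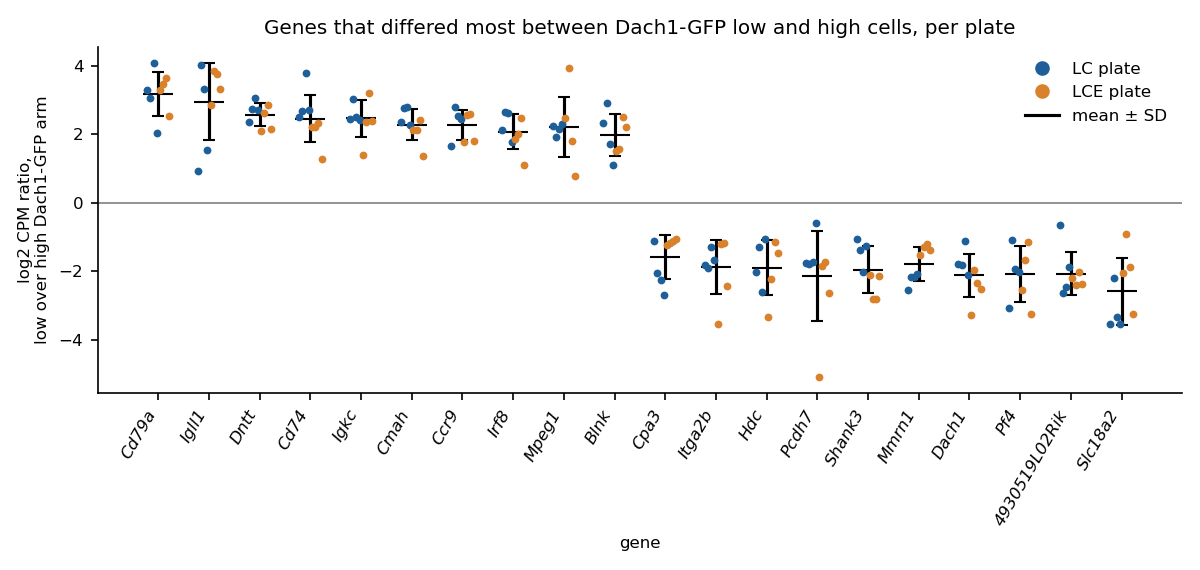
Log2 ratio of CPM, low over high Dach1-GFP arm (vertical axis), for the 10 genes with the largest rises and the 10 with the largest falls that were named by rule (horizontal axis), with 1 point per plate, LC plates in blue and LCE plates in orange, and black bars for the mean ± SD. All points of the rising genes lie above 0 and all of the falling genes below 0, with the point of Pcdh7 in replicate 5 at -5.09.

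Among cells above their plate's median CD135, which include the lymphoid-primed progenitors, low GFP went with higher RNA of lymphoid genes and lower RNA of stem cell and cell division genes. Dntt was 724 ± 214 CPM in GFP-low and 151 ± 128 CPM in GFP-high cells (log2 difference 2.52 ± 0.12, edgeR adjusted p = 3.2e-27). Hlf, a transcription factor of stem cells, was 197 ± 87.5 against 370 ± 120 CPM (-0.94 ± 0.08, edgeR adjusted p = 6.8e-14). Mecom, another stem cell transcription factor gene, was 24.3 against 49.2 CPM (-1.07 ± 0.20). Flt3 differed by 0.95 ± 0.08, Kit by -0.39 ± 0.08 and Dach1 by -1.07 ± 0.27 (13.3 ± 9.14 against 28.5 ± 13.6 CPM, edgeR adjusted p = 0.0091), each in the same direction on 8 of 8 plates. Of 7678 genes, 301 passed, 164 higher and 137 lower in GFP-low cells. CD135 was not equal between these arms, and its median was higher in the GFP-low arm on every plate. It was 5442 against 1860 in replicate 1 and 15087 against 9132 in replicate 5, so these differences are not at equal CD135.

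Besides Dntt, the largest rises were in Ccr9 (2.52 ± 0.27), Mpeg1 (2.40 ± 0.25), Cmah (2.35 ± 0.25), Arpp21, a phosphoprotein gene of brain and thymus (2.09 ± 0.24), and Cd33, a sialic acid-binding receptor gene (1.87 ± 0.25). They were followed by Slc35d3, a membrane transporter gene (1.74 ± 0.32, 3.30 on LC and 1.08 on LCE plates), Evl, an actin regulator gene (1.70), Cd74 (1.70 ± 0.18) and Il12a, the p35 subunit of interleukin-12 (1.68 ± 0.13, 185 against 62.7 CPM). Dntt differed by 3.26 within LC and 1.89 within LCE plates, and Hlf by -1.02 and -0.85. The largest falls were in Il15, the gene of interleukin-15 (-1.27 ± 0.29), Dach1 and Mecom, Myct1, a target of MYC (-1.05 ± 0.19), and the mitosis genes Kif20a (-1.02) and Cdca5 (-1.0). Smaller falls were in the mucin gene Muc13 (-0.98 ± 0.14), Itga6, the integrin alpha 6 subunit (-0.95 ± 0.16), and Spns2, a sphingosine-1-phosphate exporter (-0.94 ± 0.11).

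The lymphoid priming list had 9 of 13 genes higher and 0 lower (median 0.95, fry adjusted p = 9.9e-05), with Ighm at 527 against 246 CPM (1.16 ± 0.10) and Satb1 at 365 against 177 CPM (1.10 ± 0.09). Only 9 B lineage cells lay in the low and 2 in the high arm here, and without the cells of both kinds the list median was 0.94 and the count of genes 289. The stem cell list had 7 of 14 genes lower, 9 adjusted over the list alone (median -0.35, fry adjusted p = 0.000483), with Angpt1 at -0.78 ± 0.11. Dendritic cell genes were 2 higher of 4, 3 adjusted over the list alone (median 0.60, fry adjusted p = 0.000396), with Irf8 at 1.39 ± 0.14 and Tcf4 at 0.88 ± 0.08. All 4 mature B cell genes tested were higher (median 1.57, fry adjusted p = 0.0153), namely Cd74 and the MHC class II genes H2-Ab1 (1.30), H2-Aa (1.54) and H2-Eb1 (1.60). The G2 and M phase list had 10 of 16 genes lower, 15 adjusted over the list alone (median -0.56, fry adjusted p = 0.00126). Top2a was 320 against 442 CPM (-0.48 ± 0.07), Ube2c differed by -0.79 ± 0.15 and Ccnb2, cyclin B2, by -0.74 ± 0.16. On the LCE plates with GFP corrected for scatter, the median of this list was 0.21, against -0.45 with GFP as recorded.

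The erythroid list had 2 of 4 genes lower, 3 adjusted over the list alone (fry adjusted p = 0.00386), with Car2, a carbonic anhydrase, at -0.43 ± 0.06. Granulocyte and monocyte genes were 2 higher and 4 lower of 13, and 2 and 6 adjusted over the list alone (fry adjusted p = 0.0451, adjusted p = 0.0836 with an estimated correlation), with the granule protease genes Prtn3 (-0.46) and Ctsg (-0.62) lower and Clec12a higher (0.84). The interferon list was 1 higher of 4, 2 adjusted over the list alone (fry adjusted p = 0.0127, adjusted p = 0.0853 with an estimated correlation). The megakaryocyte (0 of 5, fry adjusted p = 0.0976), S phase (0 of 16, fry adjusted p = 0.786), immediate early (1 of 7, fry adjusted p = 0.0669), ribosomal (1 of 93, fry adjusted p = 0.0632) and mitochondrially encoded (1 of 15, fry adjusted p = 0.649) lists did not pass. The count of genes was 150 in LC and 118 in LCE plates alone, 27 without the block, 128 by DESeq2, 84 after thinning, 72 with GFP corrected for scatter, and 127 among cells with CD135 above and CD150 below the plate median. Dach1 had too few counts to be tested here without the cells of both kinds.

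Cells with high CD135 held more RNA of Flt3 and of lymphoid and dendritic genes, and less of granulocyte, erythroid and megakaryocyte genes, than cells with low CD135. Flt3 was 322 ± 86.3 CPM in CD135-high and 80.4 ± 36 CPM in CD135-low cells (log2 difference 2.09 ± 0.08, high minus low, edgeR adjusted p = 6.8e-24, 2.37 on LC and 1.80 on LCE plates). Dntt was 441 ± 159 against 113 ± 63.1 CPM (2.08 ± 0.09, 2.42 on LC and 1.77 on LCE plates). Car1, a carbonic anhydrase of red cell precursors, was 12.8 ± 10.6 against 101 ± 87 CPM (-2.97 ± 0.13, edgeR adjusted p = 5.2e-22). Dach1 was 16.6 ± 10.1 against 42.5 ± 12.1 CPM (-1.25 ± 0.18, edgeR adjusted p = 1.2e-06, -0.90 on LC and -2.26 on LCE plates). These 4 genes moved the same way on 8 of 8 plates, and 1147 of 10377 genes passed, 621 higher and 526 lower.

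The other large rises with CD135 were Cd33 (2.17 ± 0.23), Il1r1, a receptor for interleukin-1 (2.10 ± 0.18), the secreted protein gene Wfdc17 (2.10 ± 0.15, 80.4 against 19.4 CPM), Mn1, a transcriptional coregulator (2.03 ± 0.22), Evl (1.82), 5830444F18Rik (1.73), Shisa8 (1.69) and Il12a (1.67 ± 0.10). Ly6a rose by 0.48 on 7 of 8 plates (0.76 on LC and 0.10 on LCE plates), Il7r by 1.19 ± 0.33 on 6 of 8 plates (2.40 and 0.38), and Kit differed by -0.19 ± 0.06. The largest falls besides Car1 were in Ms4a3, a granulocyte and monocyte progenitor gene (-2.47 ± 0.13, 20.1 against 111 CPM), Gda, guanine deaminase (-2.44 ± 0.20), Igkc (-2.41 ± 0.10) and Ly6c2, a monocyte surface protein (-2.34 ± 0.14). Further falls were in Slc18a2 (-2.29 ± 0.22), Pf4 (-2.23), Mt1, metallothionein 1 (-2.09), Cpa3 (-1.91 ± 0.14) and Cd79a (-1.86 ± 0.23). Car1, Ms4a3, Gda, Ly6c2, Pf4 and Mt1 had enough counts for a test on the LC plates alone and not on the LCE plates alone. Of the B lineage cells, 65 lay in the CD135-low and 7 in the CD135-high arm, and without the cells of both kinds Igkc differed by -0.43 and Pf4 by -1.28, and 1008 genes passed.

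By list, 11 of 19 lymphoid priming genes were higher with CD135 and 5 lower, and the same numbers adjusted over the list alone (median 0.36, fry adjusted p = 0.00427). Satb1 was 285 against 93.3 CPM (1.66 ± 0.08), and Mef2c, a transcription factor of lymphoid and myeloid cells, differed by 0.73 ± 0.06. Without the cells of both kinds, 11 of 15 were higher and 1 lower, with a median of 0.80. Stem cell genes were 2 higher and 7 lower of 16, and 3 and 8 adjusted over the list alone (median -0.32, fry adjusted p = 0.00427). Gata2 (-1.07 ± 0.09), Apoe (-1.48 ± 0.13) and Pdzk1ip1, a membrane adaptor (-1.13), fell, and Ifitm1, an interferon-induced membrane protein of a family with shared sequence, rose (0.39). Dendritic cell genes were 3 higher of 5, 4 adjusted over the list alone (median 0.69, fry adjusted p = 0.000199), with Irf8 at 0.83 ± 0.10, Tcf4 at 0.69 and Runx2, a transcription factor of plasmacytoid dendritic cells, at 0.73.

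Granulocyte and monocyte genes were 1 higher and 9 lower of 17, and 1 and 10 adjusted over the list alone (median -0.69, fry adjusted p = 0.0135). Elane, neutrophil elastase, was 171 ± 175 against 783 ± 742 CPM (-2.22 ± 0.13, lower on 7 of 8 plates, -2.32 on LC and -1.32 on LCE plates), Mpo, myeloperoxidase, differed by -1.14 ± 0.07 and Prtn3, proteinase 3, by -1.11 ± 0.07. Fcgr3, a low-affinity IgG receptor, fell on 7 of 8 plates (-2.10 ± 0.26, -2.29 on LC and -0.42 on LCE plates). Erythroid genes were 9 lower of 10, the same number adjusted over the list alone (median -1.36, fry adjusted p = 0.00344), with Zfpm1, the GATA1 partner FOG1, at -1.13 ± 0.13 and Car2 at -0.71 ± 0.07. Megakaryocyte genes were 4 lower of 6, the same number adjusted over the list alone (median -0.64, fry adjusted p = 0.00213), with Itga2b at -1.41 ± 0.16.

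The mature B cell list had 2 of 5 genes lower with CD135 (fry adjusted p = 0.118), and without the cells of both kinds Cd74 went from -0.73 ± 0.16 to 0.03. S phase (2 lower of 16, fry adjusted p = 0.873) and G2 and M phase genes (2 higher and 1 lower of 16, fry adjusted p = 0.654) did not move one way. The immediate early (1 of 7 higher, fry adjusted p = 0.0306), interferon (2 of 8 higher, fry adjusted p = 0.00427), ribosomal (23 of 95 higher, fry adjusted p = 0.00213) and mitochondrially encoded lists (3 of 18 lower, fry adjusted p = 0.0293) were called by fry. With an estimated correlation they had an adjusted p = 0.272, adjusted p = 0.0714, adjusted p = 0.0714 and adjusted p = 0.286. Irf7, a regulator of interferon genes, rose by 1.19 ± 0.27, Jun, an immediate early transcription factor, by 0.41 and Rps24 of the small ribosomal subunit by 0.23 ± 0.03. In the LC plates alone 1096 genes passed and in the LCE plates alone 343, and the count was 169 without the block, 578 by DESeq2, 215 after thinning and 542 with CD135 corrected for scatter. Under that correction Top2a, 0.34 with CD135 as recorded on the same LCE plates, was at -0.13, and Nusap1, a spindle protein gene, went from 0.40 to -0.26.

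Cells with high CD150 held more RNA of cell division genes, and less Flt3, than cells with low CD150. Top2a was 422 ± 105 CPM in CD150-high and 289 ± 131 CPM in CD150-low cells (log2 difference 0.57 ± 0.07, high minus low, edgeR adjusted p = 3.0e-06, 0.39 on LC and 0.86 on LCE plates). Apoe was 94.4 ± 33.4 against 41.1 ± 9.61 CPM (1.24 ± 0.15, edgeR adjusted p = 1.8e-06, 1.42 on LC and 0.93 on LCE plates). Flt3 was 150 ± 58.3 against 228 ± 80.7 CPM (-0.61 ± 0.08, edgeR adjusted p = 7.2e-06), lower on 8 of 8 plates, as was Ly6a (-0.62 ± 0.11). Dach1 was 38.4 against 24.8 CPM (0.59 ± 0.18, higher on 7 of 8 plates) and did not pass (edgeR adjusted p = 0.086). Of 10398 genes, 219 passed, 161 higher (73.5%) and 58 lower.

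Of genes with a mean log2 CPM of 4 or more and the same direction on every plate, those with the largest rises were Cd79a (1.74 ± 0.27), Pf4 (1.65 ± 0.25), Apoe, Slc18a2 (1.03 ± 0.22) and 6 histone H2A genes, Hist1h2ac, Hist1h2ae, Hist1h2af, Hist1h2ag, Hist1h2ao and Gm11336, at 1.01 to 1.03. The histone genes are near-identical copies whose counts may be shared, and Hist1h2ac rose by 0.57 on LC and 1.53 on LCE plates. The falling genes were Mn1 (-1.42 ± 0.23), Pikfyve, a lipid kinase (-0.81), the long noncoding gene 9030619P08Rik (-0.68), C030034L19Rik (-0.78), Aim2, a sensor of cytosolic DNA (-0.75), Padi4, which converts arginine to citrulline in histones (-0.72), the histone demethylase gene Kdm7a (-0.64) and Tcp11l2 (-0.64). Of the B lineage cells, 58 lay in the CD150-high and 9 in the CD150-low arm, and without the cells of both kinds Pf4 differed by 0.64 (edgeR adjusted p = 0.27) and Apoe by 1.24, and 216 genes passed.

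The G2 and M phase list had 14 of 16 genes higher with CD150, 16 adjusted over the list alone (median 0.64, fry adjusted p = 0.000531). Tpx2, a spindle assembly factor, differed by 0.75 ± 0.12, Cks2, a cyclin-dependent kinase subunit, by 0.68 ± 0.11 and Hmgb2, a chromatin protein, by 0.64 ± 0.09, each higher on 8 of 8 plates. On the LCE plates the median of the list was 0.95, and 0.24 with CD150 corrected for scatter. Of 7 megakaryocyte genes, 2 were higher, 3 adjusted over the list alone (median 0.53, fry adjusted p = 0.0382, adjusted p = 0.0691 with an estimated correlation), with Itga2b at 0.70 ± 0.15. The mature B cell list had 4 of 5 genes higher, 5 adjusted over the list alone (median 0.80, fry adjusted p = 0.0382), with Cd74 at 1.10 ± 0.18. Without the cells of both kinds it had 0 of 4 genes higher and a median of 0.34 (fry adjusted p = 0.325). Of 3 macrophage genes, Vcam1, an adhesion molecule, and C1qc, a complement component, rose by 1.5 ± 0.28 each, the same 2 genes adjusted over the list alone, and Cd68 was at -0.06 (fry adjusted p = 0.0382, adjusted p = 0.0595 with an estimated correlation).

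Lymphoid priming genes were 3 higher and 4 lower of 18 with CD150, and 4 and 7 adjusted over the list alone (median -0.14, mean 0.00, fry adjusted p = 0.112). Ccr9 fell by 1.40 ± 0.23 and Dntt differed by -0.53 ± 0.10, by -0.91 on LC and -0.17 on LCE plates. Without the cells of both kinds the list had 0 higher and 4 lower of 15 genes (median -0.21, fry adjusted p = 0.00218). Stem cell genes were 3 higher and 2 lower of 17 (fry adjusted p = 0.964), with Esam, an endothelial and stem cell adhesion molecule, at 1.34 ± 0.30 (1.85 on LC and 0.51 on LCE plates) and Hlf at -0.42. Erythroid genes were 3 higher and 4 lower of 11, and 5 and 4 adjusted over the list alone (median 0.12, fry adjusted p = 0.651). Gata1, the main erythroid transcription factor, rose by 1.37 ± 0.25, and Zfpm1 by 0.68, while Hba-a1, with 34% of its counts in 1 cell, fell by 1.52. Car1 differed by 1.73 ± 0.30 over 8 plates, with opposite signs in the plate sets (2.45 on LC and -0.83 on LCE plates). Granulocyte and monocyte (1 lower of 17, fry adjusted p = 0.717), dendritic cell (0 of 5, fry adjusted p = 0.357) and S phase genes (1 higher of 16, fry adjusted p = 0.0729) did not pass as lists. Nor did the immediate early (0 of 7, fry adjusted p = 0.0729), interferon (1 lower of 8, fry adjusted p = 0.112), ribosomal (1 lower of 95, fry adjusted p = 0.206) and mitochondrially encoded lists (1 lower of 17, fry adjusted p = 0.0729). In the LC plates alone 77 genes passed and in the LCE plates alone 464, and the count was 7 without the block, 85 by DESeq2, 60 after thinning and 86 with CD150 corrected for scatter.

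**Figure D3:**
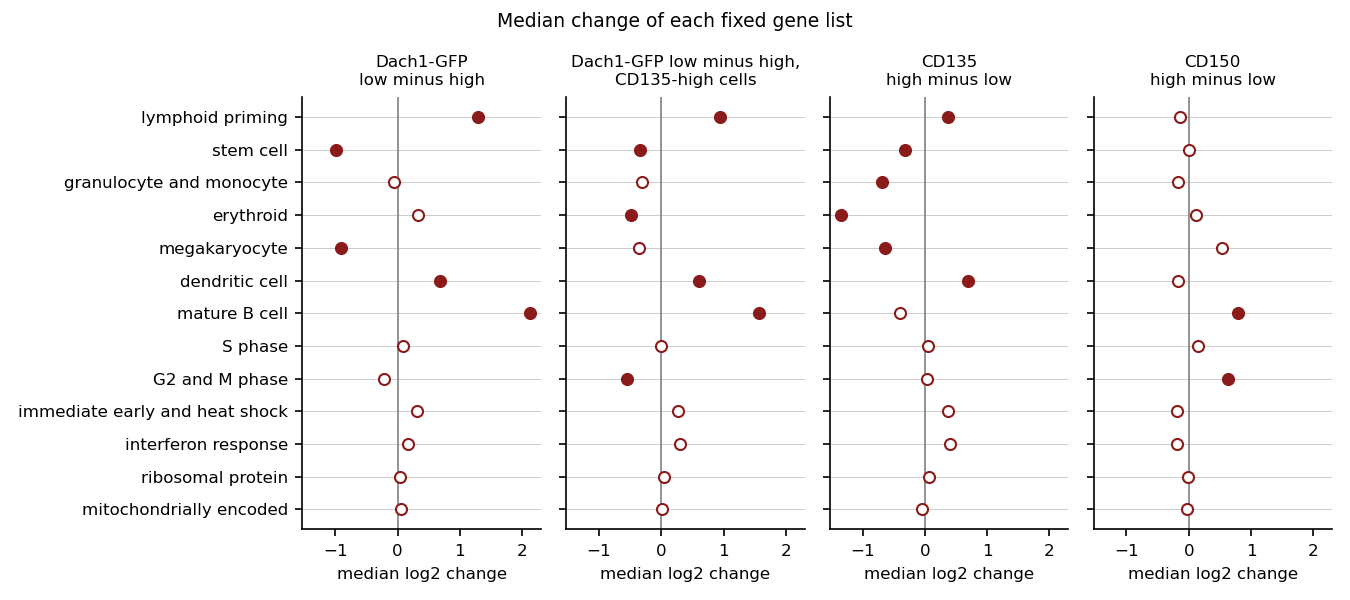
Median log2 difference over the tested genes of each fixed list (horizontal axis of each panel) in the 4 comparisons, with filled points where both fry and camera with an estimated correlation gave an adjusted p under 0.05 and open points elsewhere. The lymphoid priming list lies at 1.30 for GFP, 0.95 for GFP among CD135-high cells, 0.36 for CD135 and -0.14 for CD150.

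GFP was lower in cells with more CD135 (Spearman correlation of the fluorescence -0.50, mean over plates, from -0.574 to -0.400), so both were also fitted together. Each was split at its plate median, so cells on the same side of a split can still differ in its level. Adjusted for CD135, low GFP had 672 of 10296 genes that passed, and the lymphoid priming list had 13 of 18 genes higher and 1 lower (median 1.33, fry adjusted p = 5.4e-08). The stem cell list then had 15 of 17 genes lower (median -0.73, fry adjusted p = 2.0e-06), Dach1 differed by -1.43 ± 0.16, Flt3 by 0.47 ± 0.10 and Il7r by 2.53 ± 0.36. Adjusted for GFP, high CD135 had 902 genes that passed, with Flt3 at 1.30 ± 0.10, Fcgr3 at -1.90 ± 0.27 and Dach1 at -0.30 ± 0.15 (edgeR adjusted p = 0.245). Its erythroid list was lower in 11 of 12 genes (median -1.52, fry adjusted p = 0.00121). Its mast cell list was lower in 3 of 3 genes (median -1.21, fry adjusted p = 0.000211). Its lymphoid priming list had 7 genes higher and 6 lower of 18 (fry adjusted p = 0.50). Of the 331 cells low in both GFP and CD135, 25.7% were B lineage or the other cells set apart above, against 0.60% to 1.27% in the other 3 sums. Without these cells, low GFP adjusted for CD135 had 576 genes, with 8 of 15 lymphoid priming genes higher and 1 lower (median 0.51, fry adjusted p = 1.9e-05), 14 of 17 stem cell genes lower (median -0.68) and Dach1 at -1.31. The change was not limited to these lists. Granulocyte and monocyte genes were 10 higher and 0 lower of 17 (median 0.42, fry adjusted p = 0.0535). G2 and M phase genes were 8 lower of 16 (median -0.34, fry adjusted p = 0.000149), against 0 of 16 with these cells kept. High CD135 adjusted for GFP then had 752 genes, with the erythroid list at a median of -0.38 (6 of 11 genes lower) and 7 lymphoid priming genes higher and 2 lower of 15 (median 0.33, fry adjusted p = 0.00133).

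The difference between GFP-low and GFP-high cells also varied with CD135, by a test of that variation. GFP and CD135 are correlated, so the split can separate GFP less among CD135-high cells. The GFP-high tercile of replicate 5 had a median GFP of 752 among CD135-high and 1554 among all cells. A dependence on CD135 and this unequal split cannot be told apart here. For a gene lower in GFP-low cells, a positive value is a smaller fall, or a rise, among CD135-high cells. The difference between CD135-high and CD135-low cells in the effect of low GFP passed for 727 of 10296 genes, 337 positive and 390 negative. It was 0.97 ± 0.15 for Flt3 (edgeR adjusted p = 1.4e-06), 1.08 ± 0.30 for Dach1 (edgeR adjusted p = 0.0138), 0.46 ± 0.11 for Kit and -1.80 ± 0.47 for Fcgr3. It was positive for 12 of 17 stem cell genes (median 0.81, fry adjusted p = 1.9e-06). It was negative for 8 of 12 erythroid genes (median -2.14, fry adjusted p = 0.00449), 4 of 6 mature B cell genes (median -1.71, fry adjusted p = 0.000711) and 9 of 16 G2 and M phase genes (median -0.70, fry adjusted p = 0.000212). For lymphoid priming genes it was positive in 5 and negative in 6 of 18 (fry adjusted p = 0.916), and for the macrophage list positive in 1 of 3 (fry adjusted p = 0.0372, adjusted p = 0.194 with an estimated correlation). The sums of cells low in both held only 32 to 54 cells per plate, and those of 1 low and 1 high 116 to 135. Without the cells of both kinds, which were concentrated in the first of these, the count was 329, Flt3 was at 0.73 and 9 of 17 stem cell genes were positive (median 0.57, fry adjusted p = 0.000841). Dach1 (0.88, edgeR adjusted p = 0.0827) and Kit (0.28, edgeR adjusted p = 0.168) then did not pass. The erythroid (median -0.33, fry adjusted p = 0.0701) and mature B cell lists (median -0.51, fry adjusted p = 0.293) did not pass either, and the G2 and M phase list was called by fry alone (median -0.42, fry adjusted p = 0.0378, adjusted p = 0.101 with an estimated correlation). The granulocyte and monocyte list, not called with these cells (fry adjusted p = 0.123), was negative in 9 of 17 genes without them (median -1.11, fry adjusted p = 0.00372). Lymphoid priming genes were then positive in 5 and negative in 1 of 15 (median 0.25, fry adjusted p = 0.0676). The count was 16 without the block, and 479 without replicate 2 and 423 without replicate 4.

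The other channels were compared in the same way, high minus low. Dach1 was lower in Sca1-high (-0.47) and CD48-high cells (-0.92, 4 plates) and higher in cKit-high cells (0.92, edgeR adjusted p = 1.7e-05). Sca1 gave 1213 genes, 580 higher and 633 lower. Of its lists, 13 of 16 stem cell genes were higher (median 0.65, fry adjusted p = 0.0028) and 10 of 16 granulocyte and monocyte genes lower (median -0.76, fry adjusted p = 0.00548). By cKit, 393 genes passed. Of its lists, 12 of 17 lymphoid priming genes were lower (median -0.58, fry adjusted p = 0.00126) and 15 of 16 G2 and M phase genes higher (median 0.56, fry adjusted p = 0.00114). CD48 gave 1039 genes on 4 plates, with 15 of 16 stem cell genes lower (median -0.98, fry adjusted p = 0.0092, adjusted p = 0.068 with an estimated correlation). Forward scatter, a measure of cell size, gave 1675 genes with all 16 G2 and M phase genes higher (median 1.54, fry adjusted p = 0.00098). Side scatter, a measure of granularity, gave 696 genes with 15 of 20 lymphoid priming genes lower (median -0.70, fry adjusted p = 0.0105, adjusted p = 0.0535 with an estimated correlation). By side scatter, 5 of 5 mature B cell genes were lower too (fry adjusted p = 0.064), and B lineage cells were not left out here. IL7R gave 51, CD16/32 94, CD11b 83 and PIR-A 115 genes, the last with 13 of 20 lymphoid priming genes lower (median -0.85, fry adjusted p = 0.00515). Median counts per cell in the high over the low arm were 1.73 ± 0.08 by forward scatter, 1.56 by CD48 and 0.81 by Sca1.

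Clustering by transcriptome, without Dach1 and the genes of the sorted proteins, gave 14 clusters, and the cluster named for lymphoid priming had low GFP and high CD135. It was not the only cluster with several genes of that list among its higher genes. This lymphoid priming-like cluster held 415 cells, with Ccr9, Dntt, Lax1, Notch1 and Satb1 among its higher genes. It differed from the other cells of its plates in median arcsinh GFP by -1.47 ± 0.18 (SD, n = 8 plates) and in CD135 by 1.41 ± 0.29, each the same way on 8 of 8 plates (exact p = 0.0078, adjusted p = 0.0260). Its CD150 differed by -0.24 ± 0.12 (exact p = 0.0078, adjusted p = 0.0391), and its Dach1 RNA, 14.1 against 31.9 CPM, by -1.33 ± 1.09 on 8 of 8 plates (exact p = 0.0078, adjusted p = 0.0781). The stem cell-like cluster of 625 cells had higher GFP (0.52 ± 0.28), lower CD135 (-0.36 ± 0.25) and higher Sca1 (0.67 ± 0.17) on 8 of 8 plates, but at resolution 0.5 the cluster that overlapped it most had a CD135 difference of 0.53. The G2 and M phase-like cluster of 362 cells, with 67 to 83 cells per LC plate and 8 to 20 per LCE plate, had higher CD135 (0.55 ± 0.26) and CD150 (0.27 ± 0.11) on 7 of 7 plates. The granulocyte and monocyte-like cluster of 181 cells had 28 to 48 cells per LC plate and 5 to 8 per LCE plate, and on the 4 LC plates CD135 was at -1.21 ± 0.13 and Dach1 at -1.0 ± 0.23. An unnamed cluster of 80 cells with B lineage genes had GFP at -2.56, CD135 at -2.67 and CD150 at 1.68 (exact p = 0.125, the smallest 4 plates can give). Its higher genes held 8 of the lymphoid priming list, among them Ebf1 and Pax5, against 7 in the lymphoid priming-like cluster. An unnamed cluster of 108 cells with histone genes and 16 G2 and M phase genes among its higher genes had 23 to 29 cells per LCE plate and 0 to 1 per LC plate. Unnamed clusters of 446 cells with Pf4 and 321 cells with the interferon genes Ifit1 and Rsad2 (CD150 -0.24 ± 0.11), a macrophage-like cluster of 58 cells, and 5 clusters of 9 to 45 cells made up the rest. The cluster of 45 cells reached 10 cells on 1 plate only, replicate 8. There its higher genes held 11 of the lymphoid priming list and 15 of the G2 and M phase list. Its median GFP on that plate was 79.9, against 192 in the lymphoid priming-like cluster.

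In all, 14 differences between a cluster and the other cells passed, and 0 passed without replicate 3 or without replicate 6. In the lymphoid priming-like cluster the GFP difference then was -1.46 in both cases, and at resolution 0.5 the cluster that overlapped it most had a GFP difference of 0.14. With a plate left out the exact test cannot reach as small a p, so the fall to 0 may come from that limit.

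**Figure D4:**
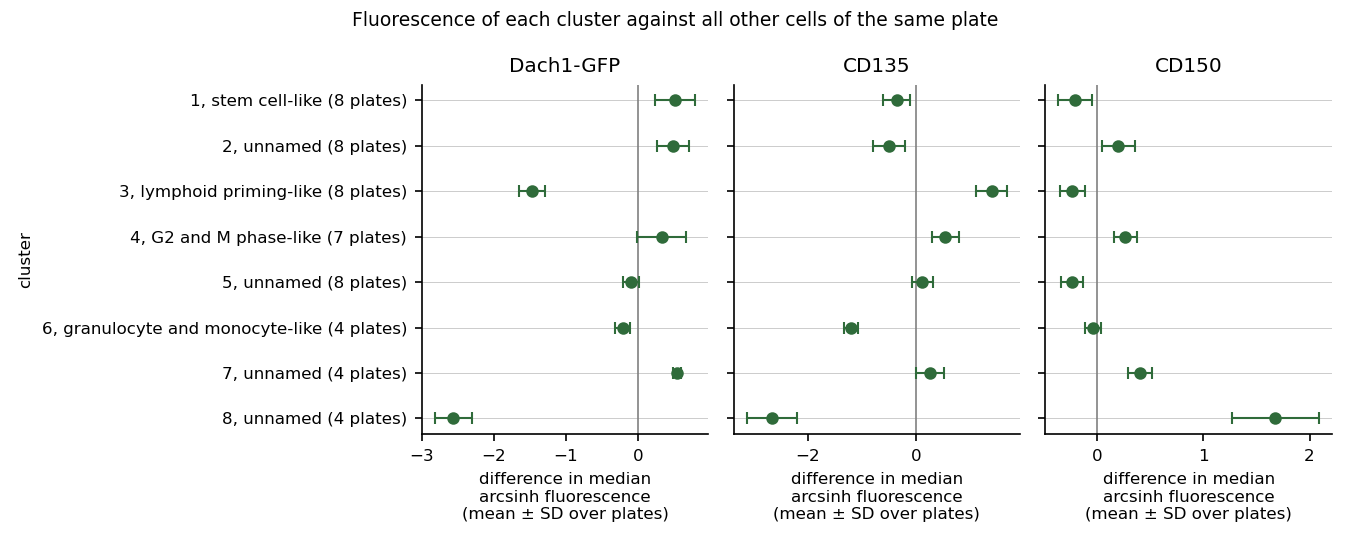
Difference in median arcsinh fluorescence of Dach1-GFP, CD135 and CD150 (horizontal axis of each panel) between each of the 8 largest clusters and all other cells of the same plate, as mean ± SD over plates with at least 10 cells of the cluster. Cluster 3, with lymphoid priming markers, lies at -1.47 for GFP and 1.41 for CD135.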

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

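The tests of other cell types and of exchanged molecules given here were chosen after the results had been seen, thinning and the correction for scatter were set before and turned to these patterns after, and the tests of immunoglobulin class and neighbouring wells were set before. The design has a single population and no groups, so no biological explanation was tested.

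In 22 of 316 sets of plate values (of named genes, of the transcripts of sorted proteins, and of depth and quality per plate), the value of 1 plate lay far from the others by Dixon's criterion, and chance does this in about 1 in 20 sets, here 16. Among them, by CD135, 5830444F18Rik was at 4.88 in replicate 3 (1.11 to 2.25 in the others), Ifi27l2a at -0.15 in replicate 3 (0.83 to 1.54), and Mcm6 at 0.64 in replicate 3 (-0.10 to 0.12). Mcpt8 was at -5.36 in replicate 3 (-2.14 to -0.34) and mt-Nd4l at -1.5 in replicate 7 (-0.44 to 0.40). By CD150, 9030619P08Rik was at -2.41 in replicate 1 (-1.06 to -0.05), Apoe at 2.69 in replicate 4 (0.71 to 1.35), Fos at 1.92 in replicate 5 (-1.03 to -0.18), and Hlf at 0.62 in replicate 4 (-0.87 to -0.28). Ly6d was at 5.69 in replicate 3 (-0.71 to 1.65) and Selp at -1.28 in replicate 2 (0.65 to 1.65). By GFP, 4930519L02Rik was at -0.63 in replicate 1 (-2.62 to -1.88), Bst2 at 0.89 in replicate 5 (0.05 to 0.44), Btg2 at 3.29 in replicate 8 (0.56 to 1.38), and Cks2 at 0.37 in replicate 5 (-0.63 to -0.31). Cmah was at 1.38 in replicate 8 (2.13 to 2.80), Igkc at 1.39 in replicate 5 (2.36 to 3.21) and Pcdh7 at -5.09 in replicate 5 (-2.62 to -0.59). By GFP among CD135-high cells, Ctsg was at -2.10 in replicate 6 (-0.82 to 0.05) and Ighm at 3.10 in replicate 3 (0.67 to 1.35).

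The LC and LCE plates differed in 18 of 300 tests of named genes (edgeR, difference of the log2 differences, LCE minus LC). By GFP, Igkc differed by -0.84 (2.68 on LC and 1.83 on LCE plates, adjusted p = 0.0155). By CD135, Dntt differed by -0.64 (2.42 and 1.77), Flt3 by -0.56 (2.37 and 1.80), Prtn3 by 0.74 (-1.32 and -0.58, adjusted p = 3.17e-06) and Igkc by 0.80 (-2.73 and -1.93). By CD150, Cd48 differed by 0.71 (-0.20 and 0.51), Dntt by 0.71 (-0.90 and -0.19), Car1 by -3.28 (2.45 and -0.83, adjusted p = 3.81e-06), Top2a by 0.47 (0.39 and 0.86), Hmgb2 by 0.64 (0.37 and 1.01) and mt-Rnr2 by -0.18 (0.03 and -0.16). The histone genes, whose counts may be shared, differed by 1.26 (Hist1h2af), 0.96 (Hist1h2ac), 0.94 (Hist1h2ae), 1.04 (Hist1h2ag), 0.97 (Gm11336) and 1.01 (Hist1h2ao). Among CD135-high cells, Dntt differed by -1.37 between the sets by GFP (3.27 and 1.90, adjusted p = 2.77e-05). The plate sets also differ in depth and in the antibodies on record, so no source of these differences can be singled out. For comparison with the scatter test, the LCE median of the G2 and M phase list by CD150 moved from 0.95 to 0.24 under that correction.

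Wells that got a cell and were left out of the comparisons still held RNA above wells that got none. With at least 100 and under 1000 counts there were 128 such wells on the LC plates, with plate medians of 335 to 380 counts, and 84 on the LCE plates, with plate medians of 179.5 to 245.5 counts, against at most 42 and 17 counts in wells without a cell. Of 34 positions with such a well on any LC plate, 29 had one on every LC plate, and 16 of 28 positions did so on the LCE plates.

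Lymphoid priming genes were higher in GFP-low cells (median 1.30), where 79 of the 86 B lineage cells lay and where counts per cell were lower (0.934 of the high arm, exact p = 0.0156, 8 plates). Without the 107 cells of other types the median was 1.15, and with each cell thinned to 3000 counts it was 1.38. Both values argue against these explanations as the whole cause in this comparison. In the fit adjusted for CD135, however, the median was 1.33 over 18 genes with the cells of other types and 0.51 over 15 genes without them. More of the list's change went with these cells there. Cells of another type with fewer marker counts than the limits used remain open, and so does a real difference between lymphoid-primed and other progenitors, which was not tested apart from this.

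The G2 and M phase list was lower in GFP-low cells among CD135-high cells (median -0.56) and higher in CD150-high cells (median 0.64). With each cell thinned to 3000 counts, and the 40 cells below that left out, the medians were -0.61 and 0.59, which argues against depth. With fluorescence corrected for scatter on the LCE plates they were 0.21 (0 of 14 genes passed by edgeR and 0 adjusted over the list alone, against 2 of 12 lower and a median of -0.45 before) and 0.24 (1 of 16 genes, against 15 of 16 and 0.95 before), as larger cells giving more fluorescence would show. Forward scatter of the high over the low arm was 1.07 and 1.09. Dividing cells are larger in any case, so a link of the reporter or of CD150 to the cell cycle and an effect of size cannot be told apart here.

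Igkc and Jchain counts appeared in many cells of the plates of replicates 2, 4, 5 and 6. Each of these plates held 1 cell with at least 200 Igkc counts, called plasma-like here (1228, 1389, 362 and 287 counts). There 50.8% to 90.4% of the other cells had an Igkc count, against 6.12% to 20.9% on the remaining plates. By the lower limit used above to leave out cells, replicates 2 and 5 each held 2 plasma cells. Replicates 1, 3, 4 and 6 each held 1 by that limit. In replicate 5, 99.1% of the switched heavy chain counts in other wells (1112 of 1122) were of the class of its plasma-like cell. This argues against free RNA from many plasma cells of mixed classes, and not against free RNA of a single class. The cell itself held 280 counts of that class, and 67.7% of Igkc counts lay in other wells there, so the class does not show that this cell was the source. In replicates 2, 4 and 6 the plasma-like cells had 0 switched heavy chain counts, so the same test decided nothing. Exchange of whole cDNA molecules would move variable and constant parts alike, but 1.77% of the variable gene's counts (2 against 111 in the cells, exact 95% interval 0.215 to 6.25, counting error only), 10.3% of those of all kappa variable genes (13 against 113) and 43.0% of Igkc counts lay in other wells. Wells next to the plasma-like cell had 1.17 times the level of those farther away (0.702 to 1.42 for random wells), which argues against spread of liquid, and exchange of short 3' fragments during pooled amplification was not tested and may be the source.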

How the results depend on the processing

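The leave-out of cells of other types, also for the lists of the fits of GFP with CD135, and the G2 and M phase list by corrected against recorded fluorescence on LCE plates were chosen after the data were seen, and the other alternatives were planned. Of the values of named genes by GFP over all settings, 1414 kept direction and side of the threshold, 121 fell short of it, 13 passed newly and 8 reversed, and by CD135, CD150 and GFP among CD135-high cells 1512, 1443 and 1479 kept both. The count of genes by GFP, CD135, CD150 and GFP among CD135-high cells (801, 1147, 219 and 301) was 444, 578, 85 and 128 by DESeq2, 272, 215, 60 and 84 with each cell thinned to 3000 counts, and 527, 542, 86 and 72 with fluorescence corrected for scatter, which leaves 4 plates. It was 450 by GFP, 77 by CD150 and 150 by GFP among CD135-high cells on LC plates alone, and 490, 343 (CD135), 464 and 118 on LCE plates alone. Among cells with CD135 above and CD150 below the median it was 127. Thinning left 498 of the 801 GFP genes tested and 236 called with the same sign. The correction for scatter left 721 of them tested, 362 called with the same sign and 17 with the opposite sign. Without the plate block, which the pairing of arms by plate calls for, the counts were 198, 169, 7 and 27, the interaction 16 in place of 727, and list calls 15 in place of 30. The other channels then had 1181 calls in place of 5359: CD48 291, Sca1 18, cKit 9, CD16/32 24, PIR-A 15, FSC-A 639, SSC-A 185, and IL7R and CD11b 0 (edgeR, 241 and 234 genes at an unadjusted p under 0.05; no other tool was run). With no filter on low counts IL7R had 115 and CD11b 128. The interaction was 329 without the 107 cells of other types, and 423 to 695 with a plate left out, 479 without replicate 2 and 423 without replicate 4. The own transcripts that passed (6) were 0 with scatter correction, 0 on LC and 0 on LCE plates alone, where 4 plates cannot pass the exact test.

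Reversed values were as follows, and the cause was not tested unless stated. With fluorescence corrected for scatter, Ube2c was at 0.57, Top2a at 0.47, Cks2 at 0.14, Hmgb2 at 0.39 and mt-Rnr2 at -0.031 by GFP, Top2a at -0.13 and Nusap1 at -0.26 by CD135, Dntt at 0.011 by CD150, and Top2a at 0.19, Ube2c at 0.18, Hmgb2 at 0.0017 and Ccnb2 at 0.40 by GFP among CD135-high cells. Top2a by GFP was at 0.0054 on LCE plates alone. Hbb-bs by GFP was at -0.19 without cells rich in plasma cell, neutrophil, globin or platelet RNA and -0.27 without both kinds of cells, and Cd74 by CD135 at 0.029 without both kinds, which removes their RNA. Cluster differences that passed (14) were 8 at resolution 0.5, 9 at resolution 1.5 and 0 to 13 with a plate left out (9 without replicate 1 or 2, 0 without 3 or 6, 4 without 7 or 8). With a plate left out the exact test cannot reach as small a p, which can lower these counts. At resolution 0.5, CD135 in clusters 1 (stem cell-like) and 2 (446 cells with Pf4) was at 0.53 and GFP in cluster 3 (lymphoid priming-like) at 0.14, and at resolution 1.5 CD135 in cluster 2 was at 0.23. With a plate left out, GFP in cluster 2 ranged from -0.38 to 0.78 and CD135 from -1.29 to 0.58, so no direction is given for this cluster. Cluster identity was matched by shared cells, so these values can belong to other cells. Arms by the authors' own sort gates were not run, since the sort records used here hold no gates.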

Other observations

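The splits of plates and arms were set before their results were seen, and the B lineage, globin-rich and platelet-rich cells were chosen after.

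CD11b, an integrin of myeloid cells, also ordered the cells by lineage genes. In CD11b-high cells 9 of 17 lymphoid priming genes were lower (median -0.39, fry adjusted p = 0.000375), and 7 of 17 granulocyte and monocyte genes were higher and 1 lower (median 0.13, fry adjusted p = 0.0388). The mature B cell list had 2 of 5 genes lower (median -0.53, fry adjusted p = 0.131, adjusted p = 0.0212 by camera with an estimated correlation), and B lineage cells were not left out here. CD16/32, the low-affinity IgG receptors of myeloid progenitors, had 8 of 19 lymphoid priming genes lower and 1 higher on the LCE plates (median -0.28, fry adjusted p = 0.0286). By CD16/32, 3 of 4 mature B cell genes were higher (median 0.86, fry adjusted p = 0.201). Cells with high CD48, a protein gained as stem cells become progenitors, had 8 of 12 granulocyte and monocyte genes higher (median 0.77) and 11 of 16 S phase genes higher (median 0.58), with fry adjusted p = 0.00456 and 0.0135. With an estimated correlation these 2 lists had an adjusted p = 0.0682 and adjusted p = 0.0937. In IL7R-high cells 6 of 16 G2 and M phase genes were higher (median 0.39, fry adjusted p = 0.0439), and 5 of 17 lymphoid priming genes (median 0.17, fry adjusted p = 0.0505).

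The 86 B lineage cells had low GFP (median percentile within the plate 4.28), low CD135 (8.54), high CD150 (83.6) and few counts (13.4). In replicate 8, however, the 13 such cells had many counts (84.1) and CD135 at 30.6, and in replicate 4 the 6 such cells had GFP at 25.15. The 11 cells rich in globin RNA had low CD135 (15.8) and many counts (97.4), and the 3 cells rich in platelet RNA had GFP and CD150 at the 99.7th percentile and CD135 at 3.55.

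Exchanging the arms within plates at random gave fewer genes than the real arms in every draw, so the share of splits with as many genes was under 0.05. The counts were GFP 801 (highest other 275, 100 splits), CD135 1147 (644), CD150 219 (49) and GFP among CD135-high cells 301 (120). The same held over 40 splits for the interaction, 727 (163), GFP adjusted for CD135, 672 (263), CD135 adjusted for GFP, 902 (521), Sca1, 1213 (723), cKit, 393 (86), IL7R, 51 (26), and CD11b, 83 (39). In each of these, 1 split, the real arms, gave as many genes. The 8 splits of the 4 LCE plates are too few for a share under 0.05, and the real and highest other counts were 1039 and 0 for CD48, 94 and 11 for CD16/32, 115 and 11 for PIR-A, 1675 and 0 for FSC-A and 696 and 2 for SSC-A. For the difference between the LC and LCE plates, the real sets gave the most genes of 35 splits by GFP (13 genes, highest other 5), CD135 (68, 7) and CD150 (66, 6). With 35 or 40 splits the smallest possible share lies not far under 0.05, and shares were not adjusted over comparisons. Chance is thus made unlikely for these counts and is not excluded. By GFP among CD135-high cells the share was not under 0.05, since 3 splits gave as many as the real 3 genes and the highest other gave 4.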
